A study of Homo sapiens with 8 samples.

How the data were processed

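RNA-seq libraries were made from LN229-TAZ(4SA) glioblastoma cells, TrxR1 knockout (KO) or control (EV), in regular or glucose-deprived medium, with 2 libraries for each of the 4 groups. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were prepared with a SMART-Seq mRNA kit and Nextera XT. That preparation does not mark strand, so overlapping and antisense genes cannot be told apart. Per the submitters' processing notes, HISAT2, edgeR and the GRCh38 genome were used, without versions. The counting tool, the annotation and any gene filter are not stated.

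The deposited table gives log2 CPM, read counts scaled to the size of each library, for 13730 genes by Entrez ID, 82 of them without a symbol. The notes do not state the scale, which was read from the values. In each library, 2 to the power of the value, less the lowest value, was a whole multiple of 1 step, within a tolerance of 0.05 for 100% of genes. The lowest value was the same in every library. That is the form of a log2 CPM with a small prior count, averaging 2 reads, scaled to each library's effective size. Values rebuilt from the whole reads differed from the deposited ones by at most 7.24e-08. Reads summed over the table are a lower bound of the depth, since genes the authors left out are not counted. CPM values printed in the text are 2 to the power of the deposited value, with the offset of 0.023 CPM removed.

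The column headers carry the group but no replicate numbers. The headers of 4 columns end in GlcN and those of the other 4 in the cell name alone. GlcN was read as the glucose-deprived medium, the labels' other condition, although the same letters also abbreviate glucosamine, which the labels do not name. TXNIP and ARRDC4, which glucose induces, were lower in those columns. The order of the 2 columns of a group gives the names a and b. Gene names are those of the table, and 13646 IDs were found in the RefSeq gene table provided. Coordinates are from GENCODE release 29 on GRCh38.

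Genes with a mean log2 CPM of at least 0 were tested (13057 genes, with 673 below). The deposited log2 values were fitted with limma 3.58.1 in R 4.3.3, in 1 linear model over the 4 groups with 4 residual degrees of freedom and a variance trend with expression. The prior had 6.29 degrees of freedom. The 5 contrasts were KO against EV in each medium, glucose-deprived against regular medium in each cell type, and their interaction. P-values are two-sided and adjusted by Benjamini-Hochberg over the genes tested in a contrast. A gene was called at an adjusted p under 0.05. Standard errors are limma's moderated ones. The p-values measure the spread between these libraries, which the labels do not describe as separate cultures.

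Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, over the 28 lists with at least 5 tested members, adjusted by Benjamini-Hochberg. Camera compares a list's genes with the other genes. Beside it were run fry, which tests a list without comparing it with others, and camera with the correlation estimated per list. In limma that estimate also lowers the degrees of freedom of the test. Calls could thus be lost without a higher correlation. YAP/TAZ targets for KO against EV in regular medium, at an estimated correlation of -0.022, went from adjusted p = 4.3e-05 to 0.082. A call lost in that test therefore does not show that the genes of a list were correlated. Of 31 lists, 3 were not tested: mitochondrially encoded mRNAs (0 of 13 in the table), metallothioneins (4 genes tested) and leukocyte markers (2 genes tested). HSPA1A, HSPA1B and RPS18 were likewise absent from the table and not analysed here.

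The lists, tests, filter, alternatives and the rule for naming genes were chosen before the data were examined. The rule names a panel of 14 genes, the 8 largest rises and 8 largest falls per contrast among called genes whose libraries did not overlap and whose higher group had at least 10 CPM, and up to 3 called members of each list by smallest adjusted p. Any other gene is said to have been chosen after its values were seen.

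The steps were tested on simulated reads drawn from the means and sizes of these libraries, with 50 genes changed at each of 4 fold sizes among 13057. For KO against EV in regular medium, 64% of genes changed 1.25-fold, 86% at 1.5-fold and 100% at 2-fold were called in the right direction, and 8.85% of 192 calls were false. In glucose-deprived medium these were 48%, 84% and 94%, with 4.68% of 171 calls false. For deprivation they were 50%, 82% and 92% in EV cells (7.43% of 175 calls false) and 54%, 76% and 96% in KO cells (7.91% of 177 false). For the interaction they were 22%, 54% and 80%, with 5.19% of 135 calls false. None of 30 unchanged lists was called in any contrast, that is 0 of 30. The simulated genes were drawn independently, whereas the estimated correlation in the real lists reached 0.45 (aminoacyl-tRNA synthetases). The simulation therefore cannot show how often lists of correlated genes are falsely called. It also changed few genes, took the library sizes as known and gave all groups the same spread. In the real data 76.2% of genes were called on deprivation of EV cells and 73.3% on deprivation of KO cells. The simulated rates therefore do not describe those calls.

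Alternatives were other offsets before log2 (0.1 and 5 CPM), no filter and a 5 times higher minimum mean, median-of-ratios scaling and quantile normalization, limma without the trend, with robust estimation or with library weights, fits of the compared groups alone, a fold threshold, and leaving out each library in turn. Tests with edgeR or DESeq2 on counts were not run, although whole reads could be recovered from the log2 values. Limma's voom on the recovered reads was added in their place after the data were seen.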

Results

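The series measured mRNA levels by RNA-seq in LN229-TAZ(4SA) cells, a derivative of the human glioblastoma line LN229 that the labels name by a TAZ(4SA) construct. Knockout (KO) cells lacked TrxR1, the cytosolic thioredoxin reductase encoded by TXNRD1, according to the labels, and control cells are labelled EV. Each was kept in regular or glucose-deprived medium, and each of the 4 groups had 2 libraries. The libraries of a group are called a and b here, which are only names. The columns taken as glucose-deprived carry the suffix GlcN, which the labels do not explain. The comparisons ask how loss of TrxR1 and lack of glucose act on the cells, alone and in combination. The labels do not say how many knockout clones were used, so other differences between KO and EV cells cannot be told apart from loss of TrxR1. Whole reads could be recovered from the deposited log2 CPM values (read counts scaled to the size of each library), and summed to 70083018 to 107229069 reads per library. At this depth 1 read was worth 0.0095 to 0.0143 CPM. Of 13730 genes in the table, 13057 passed the filter on mean expression and were tested.

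Libraries of a group correlated at r = 0.9969 to 0.9983 across genes, KO and EV libraries in the same medium at 0.9937 to 0.9966, and libraries from different media at 0.9578 to 0.9642. Genes are not independent replicates in these values. The leading principal component held 86.6% of the variance and separated the media. No 2 libraries agreed within counting error, the chi-square per gene between libraries of a group being 3.84 to 18.96. The labels do not say that libraries came from separate cultures, so the p-values measure only the spread between these libraries, which can be technical.

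TXNRD1, the targeted gene (Entrez 7296; GRCh38 chromosome 12, 104215779 to 104350305, plus strand, protein-coding), had nearly equal mRNA levels in KO and EV cells in regular medium. Its level was 261.7 ± 1.5 CPM in EV and 247.2 ± 3.3 CPM in KO cells (SD, n = 2), a log2 fold change of -0.083 ± 0.036 (SE, limma adjusted p = 0.19). In glucose-deprived medium it was 500.7 ± 11.3 CPM in EV and 360.6 ± 13.8 CPM in KO cells, a fall of -0.47 ± 0.036 (adjusted p = 2.0e-05). The interaction was -0.39 ± 0.050 (adjusted p = 0.0025). The values are totals per gene and do not show whether an edited exon or the protein was changed, so the mRNA level does not test the knockout label.

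**Figure D1:**
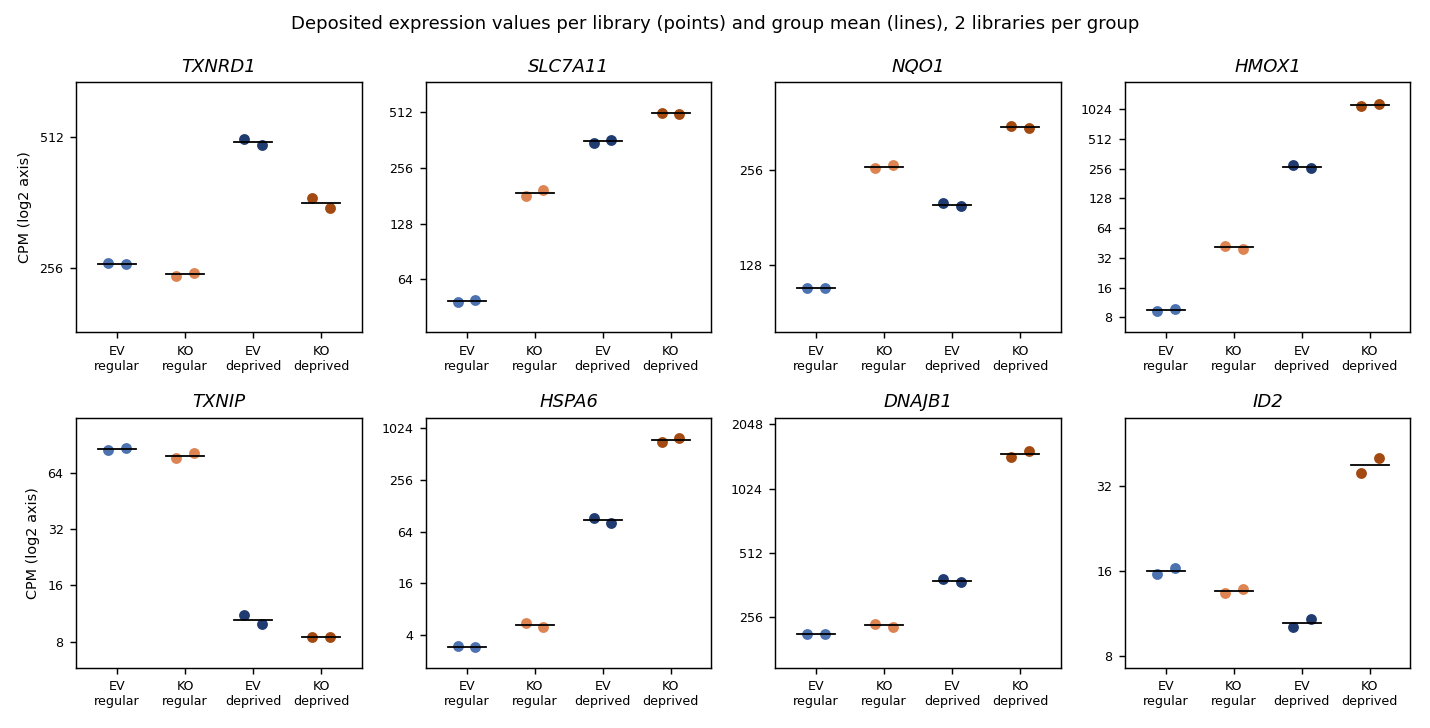
Expression of 8 genes in each library, as CPM (2 to the power of the deposited log2 CPM) on a log2 axis whose range differs between panels. Points are libraries, horizontal lines are means of 2 libraries. TXNRD1 lies near 250 CPM in both regular-medium groups, whereas HSPA6 reaches 734 CPM in the glucose-deprived KO libraries against 86.5 CPM in the EV libraries.

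In regular medium KO cells carried higher levels of the targets of NRF2, the transcription factor of the oxidative stress response. HMOX1, heme oxygenase 1, rose from 9.55 ± 0.35 to 41.0 ± 1.8 CPM, a log2 fold change of 2.10 ± 0.049 (adjusted p = 4.0e-09). SLC7A11, the cystine importer of system xc-, rose from 48.7 ± 0.79 to 187.1 ± 10.4 CPM (1.94 ± 0.041, adjusted p = 3.1e-09). NQO1, a quinone reductase, rose from 107.8 ± 0.14 to 262.8 ± 3.3 CPM (1.29 ± 0.031, adjusted p = 4.2e-09). OSGIN1 rose by 1.79, TRIM16L by 1.70 and FTL, the ferritin light chain, by 1.06. Not on the list of NRF2 targets tested, the pseudogene NMRAL2P rose by 3.43 and TRIM16 by 1.17. TRIM16 and TRIM16L share near-identical sequence, as does FTL with pseudogenes, and their reads cannot be told apart here. HMOX1 lies on chromosome 22 (35380361 to 35394214), SLC7A11 on chromosome 4 (138164097 to 138242349) and NQO1 on chromosome 16 (69706996 to 69726951) of GRCh38.

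Of 32 measured NRF2 targets, 28 rose and 0 fell in KO cells, with the same counts adjusted over the list alone (median log2 fold change 0.64, camera adjusted p = 2.2e-48). This was the list whose call held with an estimated correlation (adjusted p = 0.0019). In the thioredoxin, peroxiredoxin and glutathione list 10 of 39 genes rose, among them SRXN1, GCLM and GSR, which recycle peroxiredoxin or make and reduce glutathione (0.89, 0.93 and 0.67). Adjusted over the list alone 12 rose, and the list was called higher (adjusted p = 1.9e-05) but had an adjusted p = 0.27 with an estimated correlation. Of 33 ATF4 targets 15 rose and 1 fell, or 19 and 1 adjusted over the list alone (adjusted p = 8.5e-13, and adjusted p = 0.082 with an estimated correlation). SLC7A11 belongs to this list as well, and other risers were STC2 (0.48) and PPP1R15A, a phosphatase subunit that acts on eIF2 (0.54). ATF4 itself rose by 0.26 ± 0.034 (adjusted p = 0.0015), while DDIT3 (0.13, adjusted p = 0.091) and ASNS (0.065, adjusted p = 0.37) did not pass.

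Endoplasmic reticulum chaperones were lower in KO cells. Of 25 measured, 10 fell and 1 rose, or 18 and 1 adjusted over the list alone (adjusted p = 6.0e-10, and adjusted p = 0.18 with an estimated correlation). HSPA5, the main chaperone of this compartment, changed by -0.38, MANF by -0.32 and PDIA4 by -0.30. Of 65 cytosolic ribosomal protein genes 21 rose and 0 fell, or 44 rose adjusted over the list alone, by a median of 0.12 (adjusted p = 4.8e-18, and adjusted p = 0.18 with an estimated correlation). Of 24 YAP/TAZ targets 7 rose, or 11 adjusted over the list alone (adjusted p = 4.3e-05, and adjusted p = 0.082 with an estimated correlation), led by CCN1 at 0.42 ± 0.037 (adjusted p = 1.2e-04). Among 36 autophagy and lysosome genes 6 rose, or 10 adjusted over the list alone (adjusted p = 2.9e-04, and adjusted p = 0.082 with an estimated correlation), including the cargo receptor SQSTM1 (0.73), GLA (0.43) and GABARAPL1 (0.56). Of 19 cytosolic heat shock genes 5 rose, or 9 with 1 fall adjusted over the list alone (median 0.11, adjusted p = 1.1e-04, and adjusted p = 0.13 with an estimated correlation).

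Among genes called in regular medium, the largest falls were smaller than the largest rises, with 0 called genes falling and 17 rising by 1 or more on the log2 scale. STARD4-AS1 changed by -0.60, MAF by -0.55, ERBB3 by -0.54 and SOX2, a stem cell transcription factor used as a glioma marker, by -0.51. Falls of FAM222A (-0.58), EGR3 (-0.57), SEMA3B (-0.51) and PLXNB3 (-0.50) each lost their call without EV regular a (adjusted p = 0.109 to 0.26) or EV regular b (0.054 to 0.15). Without strand information, STARD4-AS1 reads cannot be told apart from those of STARD4, which itself fell (-0.40). Lists of aminoacyl-tRNA synthetases, glycolysis, pentose phosphate pathway, oxidative phosphorylation and NF-kB genes were called higher, and those of cholesterol synthesis, p53 targets and interferon response lower. Of these 8 lists at most 6 members rose and at most 3 fell (0 of 48 for oxidative phosphorylation), or at most 9 and 6 adjusted over the list alone. Their adjusted p = 0.18 to 0.44 with an estimated correlation. Fry did not call the aminoacyl-tRNA synthetase (adjusted p = 0.12), oxidative phosphorylation (0.12), NF-kB (0.088) and interferon (0.20) lists. The pentose phosphate list was called higher with a median of -0.00029 and a mean of 0.14, its calls being led by TALDO1 (0.65) and TKT (0.59), and its median turned positive with median-of-ratios scaling.

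In total 946 genes were called in regular medium, 505 higher and 441 lower, with a median SE of 0.055. The lower ones were slightly more numerous without the variance trend (214 and 219) and without KO regular a (257 and 260) or KO glucose-deprived a (699 and 709) or b (703 and 711), whereas median-of-ratios scaling gave 601 higher and 397 lower. The count fell to 168 and 198 without EV regular a or b, to 517 without KO regular a, and to 581 and 573 without EV glucose-deprived a or b. With 1 library left out, called NRF2 targets numbered 24 to 28 and called ribosomal protein genes 0 (without EV regular a or b) to 38. Without EV regular a or b the rising ATF4 targets numbered 6 and 6, the falling endoplasmic reticulum chaperones 3 and 6, and the rising YAP/TAZ targets 2 and 1. The rising heat shock genes then numbered 0 and 1, autophagy genes 4 and 4, glycolysis genes 0 and 0, and NF-kB genes 1 and 1. Without KO regular a 10 ATF4 targets, 2 glycolysis and 2 NF-kB genes rose, and without KO regular b 2 heat shock genes. Without EV glucose-deprived a or b, 1 heat shock and 3 glycolysis genes rose. The calls of the interferon list (adjusted p = 0.51 without EV regular a) and of oxidative phosphorylation (adjusted p = 0.15 without EV regular b and 0.082 without KO regular b) ended. The CCN2 rise of 0.25 lost its call without EV regular a (adjusted p = 0.062) or b (0.051).

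In glucose-deprived medium the knockout was accompanied by higher levels of cytosolic heat shock genes as well as of NRF2 targets. HSPA6, an inducible HSP70, reached 734.2 ± 58.3 CPM in KO cells against 86.5 ± 8.8 CPM in EV cells, a log2 fold change of 3.09 ± 0.077 (adjusted p = 4.1e-09). It lies on chromosome 1 (161524540 to 161526910) and shares sequence with HSPA1A and HSPA1B, which were not analysed here, so reads of these genes cannot be told apart here. DNAJB1, an HSP40 co-chaperone, rose from 378.8 ± 9.5 to 1489.7 ± 60.5 CPM (1.98 ± 0.037, adjusted p = 8.3e-10). HSPH1 rose by 1.69 and BAG3 by 1.49. Of 19 measured heat shock genes 18 rose and 0 fell, and 19 rose adjusted over the list alone (median 0.87, adjusted p = 1.0e-30). The list's call held with an estimated correlation (adjusted p = 0.0075).

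Of 32 NRF2 targets 29 rose and 0 fell, or 30 adjusted over the list alone (median 0.59, adjusted p = 3.3e-32, and adjusted p = 0.0044 with an estimated correlation). HMOX1 rose from 268.4 ± 13.6 to 1128.8 ± 35.1 CPM (2.07 ± 0.049, adjusted p = 3.0e-09), NQO1 by 0.82 ± 0.031 (adjusted p = 1.6e-07) and SLC7A11 by 0.50 ± 0.041 (adjusted p = 3.6e-05). SLC3A2, the partner chain of SLC7A11, rose by 0.39 ± 0.051 (adjusted p = 7.2e-04). In regular medium its rise of 0.30 (adjusted p = 0.0081) lost its call without EV regular a (adjusted p = 0.062), EV regular b (0.087) or KO regular a (0.0501). Of 39 thioredoxin, peroxiredoxin and glutathione genes 12 rose and 3 fell, with the same counts adjusted over the list alone (adjusted p = 0.0012, and adjusted p = 0.40 with an estimated correlation).

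Mitosis genes were lower in KO cells in glucose-deprived medium. Of 35 measured, 28 fell and 0 rose, or 32 adjusted over the list alone, by a median of -0.26 (adjusted p = 1.0e-19, and adjusted p = 0.27 with an estimated correlation). KIF20A, a kinesin of cytokinesis, changed from 257.3 ± 14.3 to 180.7 ± 7.4 CPM (-0.51 ± 0.043, adjusted p = 4.2e-05), the kinase PLK1 by -0.39 and the cyclin CCNB1 by -0.36. DNA replication genes went the other way, with 16 of 38 higher and 3 lower, or 21 and 3 adjusted over the list alone (adjusted p = 1.2e-05, and adjusted p = 0.29 with an estimated correlation). SLBP, which processes histone mRNAs, rose by 0.24, whereas the helicase subunit MCM7 fell (-0.30).

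Immediate early genes, which respond within minutes to many stimuli, were also higher, with 16 of 24 rising and 2 falling, or 18 and 2 adjusted over the list alone (median 0.34, adjusted p = 1.3e-10, and adjusted p = 0.29 with an estimated correlation). FOS rose by 1.70 ± 0.088, DUSP1 by 1.42 and IER5 by 1.21. Of 33 ATF4 targets 13 rose and 3 fell, or 17 and 4 adjusted over the list alone (adjusted p = 0.0011, and adjusted p = 0.29 with an estimated correlation), ATF3 by 0.74 and CHAC1, which degrades glutathione, by 0.52. ATF4 (-0.030, adjusted p = 0.57), DDIT3 (-0.068, adjusted p = 0.28) and ASNS (-0.039, adjusted p = 0.56) did not pass. Of 25 endoplasmic reticulum chaperones 13 fell and 1 rose, with the same counts adjusted over the list alone (adjusted p = 4.1e-05, and adjusted p = 0.37 with an estimated correlation), HYOU1 by -0.31, while XBP1 rose by 0.24. Of 24 p53 targets 9 fell and 2 rose, or 12 and 3 adjusted over the list alone (adjusted p = 0.0012, and adjusted p = 0.26 with an estimated correlation), MDM2 by -0.27. The inhibitor of differentiation ID2 rose from 10.5 ± 0.50 to 37.8 ± 3.1 CPM (1.85 ± 0.066), and RGS2 by 1.60. The largest falls were those of LINC01583 (-0.75), CTDSP1 (-0.66), PIF1 (-0.57) and TMEM106A (-0.53). Falls of FGFBP2 (-0.53, adjusted p = 0.13 without EV glucose-deprived a and 0.093 without KO glucose-deprived b) and CNOT3 (-0.49, adjusted p = 0.30 without EV glucose-deprived a) lost their calls.

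Smaller shifts were called in 3 more lists. Autophagy and lysosome genes rose for 9 of 36 members and fell for 3, or 11 and 3 adjusted over the list alone (adjusted p = 0.0078, and adjusted p = 0.26 with an estimated correlation). Glycolysis genes rose for 6 of 24 and fell for 2, or 7 and 2 adjusted over the list alone (adjusted p = 0.0081, and adjusted p = 0.44 with an estimated correlation). In the pentose phosphate list 5 of 19 rose and 2 fell, with the same counts adjusted over the list alone (adjusted p = 0.048, and adjusted p = 0.29 with an estimated correlation). Its call ended without EV glucose-deprived b (adjusted p = 0.077), KO glucose-deprived a (0.074) or KO regular a or b (both 0.053). YAP/TAZ targets were not called by camera (6 of 24 higher and 5 lower, median -0.010, adjusted p = 0.57), whereas fry called them higher (adjusted p = 0.012). CCN1 was at 0.027 (adjusted p = 0.65) and CCN2 at -0.060 (adjusted p = 0.28).

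In total 2561 genes were called in glucose-deprived medium, 1181 higher and 1380 lower, but 499 and 393 without EV glucose-deprived a, 450 and 402 without b, and 834 and 706 without KO glucose-deprived b. Of these 35 rose and 0 fell by 1 or more on the log2 scale. The count fell to 892 and 852 without EV glucose-deprived a or b and to 1540 without KO glucose-deprived b. With 1 library left out 17 to 18 heat shock genes and 25 to 30 NRF2 targets were called higher, 19 to 32 mitosis genes and 4 to 13 endoplasmic reticulum chaperones lower, and 3 to 18 DNA replication genes and 10 to 18 immediate early genes higher. Without EV glucose-deprived a or b the rising ATF4 targets numbered 7 and 7 (also 7 without KO glucose-deprived b), the falling p53 targets 5 and 5, and the rising autophagy genes 5 and 5. Rising glycolysis genes numbered 4 without any of the EV libraries.

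In EV cells, glucose deprivation lowered the thioredoxin-binding arrestin gene TXNIP, whose transcription follows glucose, and raised genes of amino acid and endoplasmic reticulum stress. TXNIP (chromosome 1, 145992435 to 145996600) went from 86.3 ± 1.1 to 10.5 ± 0.80 CPM, a log2 fold change of -3.04 ± 0.057 (adjusted p = 2.2e-11), and its relative ARRDC4 changed by -1.37 ± 0.12 (adjusted p = 1.7e-06). DDIT3, the stress factor CHOP, rose from 17.5 ± 0.18 to 426.0 ± 13.3 CPM (4.60 ± 0.042, adjusted p = 2.3e-13), ASNS, asparagine synthetase, by 2.48 ± 0.042 and ATF4 by 1.33 ± 0.034. Of 33 ATF4 targets 31 rose and 1 fell by a median of 1.82 for the list (adjusted p = 3.3e-15, and adjusted p = 0.082 with an estimated correlation), with the same counts adjusted over the list alone. All 25 endoplasmic reticulum chaperones and unfolded protein response genes rose, also when adjusted over the list alone, by a median of 2.10 (adjusted p = 4.8e-15, and adjusted p = 0.14 with an estimated correlation). HERPUD1, a degradation factor of this compartment, rose by 4.51, and HSPA5 by 3.19, from 966.6 ± 12.1 to 8796.2 ± 346.3 CPM. Of 19 aminoacyl-tRNA synthetase genes 14 rose and 4 fell, with the same counts adjusted over the list alone (adjusted p = 0.0017, and adjusted p = 0.51 with an estimated correlation), AARS1 by 2.45 and WARS1 by 2.34.

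Of 32 NRF2 targets 28 rose and 3 fell on deprivation of EV cells, with the same counts adjusted over the list alone (median 0.80, adjusted p = 1.2e-08, and adjusted p = 0.063 with an estimated correlation). HMOX1 rose by 4.81 ± 0.049 (adjusted p = 5.4e-13) and SLC7A11 by 2.87 ± 0.041 (adjusted p = 4.4e-12). SLC3A2 rose by 1.13 ± 0.051, NQO1 by 0.88 ± 0.031 and TXNRD1 by 0.94 ± 0.036. Cytosolic heat shock genes were lower as a list, with 16 of 19 falling and 3 rising, the same counts as adjusted over the list alone (median -0.72, adjusted p = 2.2e-04, and adjusted p = 0.14 with an estimated correlation). DNAJA1 changed by -1.40 and HSPA8, the constitutive HSP70, by -1.35. HSPA6, which is not on this list, rose by 4.88 ± 0.077, from 2.92 ± 0.061 to 86.5 ± 8.8 CPM. GDF15, a stress-induced cytokine, rose by 4.64.

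Growth and cytoskeleton genes were lower. Of 38 DNA replication genes 28 fell and 4 rose (adjusted p = 6.7e-05, and adjusted p = 0.29 with an estimated correlation), of 35 mitosis genes 23 fell and 4 rose (adjusted p = 0.0058, and adjusted p = 0.57 with an estimated correlation), and of 45 WAVE complex and actin genes 32 fell and 7 rose (adjusted p = 0.0013, and adjusted p = 0.29 with an estimated correlation). UHRF1 changed by -1.63, the kinase AURKA by -1.10 and the tropomyosin TPM1 by -0.95. YAP/TAZ targets fell for 17 of 24 members and rose for 5 (adjusted p = 0.011, and adjusted p = 0.16 with an estimated correlation), AJUBA by -1.17 and CCN2 by -0.61, while CCN1 was at 0.057 (adjusted p = 0.18). The BMP-responsive genes ID1 and ID3 were among the largest falls (-3.22 and -3.13). Adjusted over the list alone, the counts of these 4 lists were the same.

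Other lists called higher in EV cells were ribosomal proteins with 55 of 65 rising and 2 falling (median 0.27, adjusted p = 0.38 with an estimated correlation) and autophagy and lysosome genes with 26 of 36 rising and 3 falling (0.082), WIPI1 by 3.18. Hypoxia response genes rose for 14 of 21 members and fell for 4 (adjusted p = 0.16 with an estimated correlation), VEGFA by 2.48. NF-kB and inflammatory genes rose for 17 of 22 and fell for 5 (adjusted p = 0.50 with an estimated correlation), PTGS2, the inducible cyclooxygenase, by 3.68. Interferon response genes rose for 16 of 26 and fell for 4 (adjusted p = 0.51 with an estimated correlation), immediate early genes for 14 of 24 and 5 (0.57), and pentose phosphate and NADPH genes for 13 of 19 and 3 (0.19), with MTHFD2, a mitochondrial folate enzyme, at 1.89. Adjusted over the list alone, 56 ribosomal protein genes rose and the other counts were the same. In total 9955 genes were called, 4902 higher and 5053 lower, and 783 rose and 454 fell by 1 or more on the log2 scale. No list kept its call with an estimated correlation, against 16 lists with the preset correlation.

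In KO cells, glucose deprivation changed much the same genes, and the heat shock genes apart. TXNIP went from 79.6 ± 3.3 to 8.45 ± 0.025 CPM (-3.23 ± 0.057, adjusted p = 1.7e-11). DDIT3 rose by 4.41 ± 0.042, HMOX1 by 4.78 ± 0.049, ASNS by 2.38 ± 0.042, ATF4 by 1.04 ± 0.034, SLC7A11 by 1.44 ± 0.041 and TXNRD1 by 0.54 ± 0.036. HSPA6 rose by 7.11 ± 0.077, from 5.28 ± 0.35 to 734.2 ± 58.3 CPM, DNAJB1 by 2.67 and FOS by 3.61. Of 19 heat shock genes 7 rose and 8 fell, and camera did not call the list (median -0.068, mean 0.20, adjusted p = 0.998). Fry, which does not compare a list with other genes, called it higher (adjusted p = 5.5e-05). Of 33 ATF4 targets 31 rose and 2 fell (adjusted p = 0.071 with an estimated correlation), of 25 endoplasmic reticulum chaperones 25 rose (0.11), and of 32 NRF2 targets 29 rose and 1 fell (0.071). Immediate early genes rose for 19 of 24 members and fell for 3 (adjusted p = 0.49 with an estimated correlation). Mitosis genes fell for 30 of 35 members and rose for 1 (median -0.41, adjusted p = 7.8e-08, and adjusted p = 0.48 with an estimated correlation), AURKA by -1.44. Adjusted over the list alone, these counts were the same.

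The remaining lists called in KO cells were DNA replication (25 of 38 lower and 5 higher), WAVE complex and actin genes (33 of 45 lower and 6 higher), YAP/TAZ targets (17 of 24 lower and 3 higher) and oxidative phosphorylation (22 of 48 lower and 6 higher). Called higher were ribosomal proteins (39 of 65, with 4 lower), autophagy and lysosome genes (26 of 36, with 2 lower), hypoxia response (15 of 21, with 4 lower), interferon response (18 of 26, with 3 lower), NF-kB genes (15 of 22, with 4 lower), aminoacyl-tRNA synthetases (14 of 19, with 4 lower) and the pentose phosphate list (12 of 19, with 3 lower). Their adjusted p = 0.071 to 0.54 with an estimated correlation. Adjusted over the list alone, 5 oxidative phosphorylation and 13 pentose phosphate genes were higher and the other counts were the same. The oxidative phosphorylation call ended without KO regular b (adjusted p = 0.061) or KO glucose-deprived b (0.058), and with quantile normalization (0.29). In total 9572 genes were called, 4766 higher and 4806 lower, with 738 rising and 281 falling by 1 or more on the log2 scale.

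WWTR1, the gene of TAZ, changed little between groups. Its log2 fold change was -0.16 in KO cells in regular medium (adjusted p = 0.024), -0.11 in glucose-deprived medium (adjusted p = 0.049) and -0.12 on deprivation of EV cells (adjusted p = 0.0093). These calls were lost without EV regular a (adjusted p = 0.20, 0.099 and 0.061), EV regular b (0.17, 0.099 and 0.051) and other libraries. On deprivation of KO cells it was at -0.074 (adjusted p = 0.081). The labels name these cells by a TAZ construct, whose reads could count toward WWTR1. Totals per gene cannot tell such reads from those of the cells' own gene, so the level of that gene alone was not measured. Every library came from cells with this construct in their name, so the results for YAP/TAZ targets apply to such cells only. TXNIP was at -0.12 in KO against EV cells in regular medium (adjusted p = 0.25) and at -0.31 in glucose-deprived medium (adjusted p = 0.0050), where its call was lost without EV glucose-deprived a (adjusted p = 0.053). On deprivation of KO cells CCN1 changed by -0.34 and CCN2 by -0.92.

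The responses of EV and KO cells to deprivation overlapped widely. Called in the same direction in both were 8497 genes, 4236 higher and 4261 lower, against 1789.3 and 1859.9 for independent lists, and 54 genes were called in opposite directions. Across 13057 genes the log2 fold changes correlated at Pearson r = 0.931 and Spearman rho = 0.922, though genes are not independent. The knockout effects in the 2 media shared fewer calls. In the same direction 424 genes were called, 222 higher and 202 lower, against 45.7 and 46.6 for independent lists, and 45 were opposite, with r = 0.218 and rho = 0.221 across genes. Of the 946 genes called in regular medium, 78.96% had the same sign in glucose-deprived medium, and of the 9955 called on deprivation of EV cells, 96.5% had the same sign in KO cells. The count of 424 fell to 117 and 134 without EV regular a or b, and to 198 and 179 without EV glucose-deprived a or b. The comparisons set side by side share no library.

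**Figure D2:**
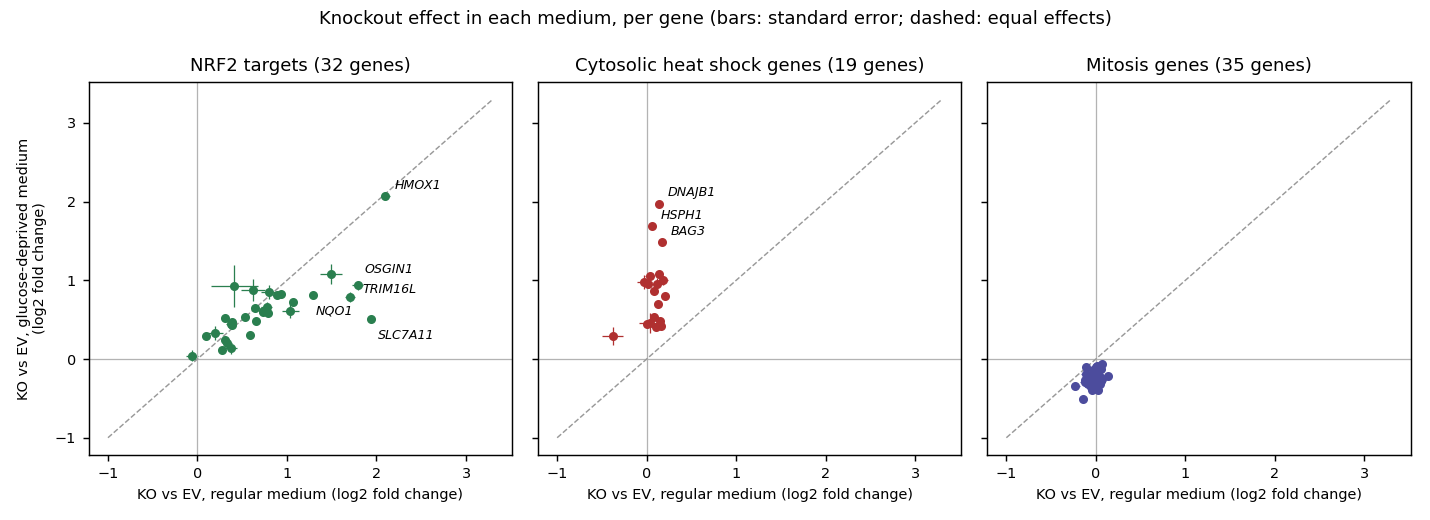
Log2 fold change of KO against EV in regular medium (x axis) and in glucose-deprived medium (y axis) for members of 3 gene lists, with standard errors as bars and a dashed line of equal effects. All but 1 of the 32 NRF2 targets lie above 0 on both axes, with SLC7A11 below the line, the 19 heat shock genes lie above the line with a median of 0.87 on the y axis, and the 35 mitosis genes have a median of -0.26 there.

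The interaction tests whether the knockout effect differed between the media. Among lists, heat shock genes had the highest median. HSPA6 was 2.24 ± 0.11 higher on the log2 scale than the separate effects add up to (adjusted p = 2.4e-06), DNAJB1 1.84 ± 0.052 (adjusted p = 4.5e-08), HSPH1 1.63 ± 0.048 (adjusted p = 4.5e-08) and BAG3 1.32. Of 19 heat shock genes 18 were higher, or 19 adjusted over the list alone (median 0.79, adjusted p = 3.8e-33), and the call held with an estimated correlation (adjusted p = 0.013). ID2 had an interaction of 2.09 ± 0.094, FOS of 1.98 ± 0.12, RGS2 of 1.5 and EGR3 of 1.51. That of IER5L (1.84) lost its call without any library but the KO glucose-deprived ones (adjusted p = 0.058 to 0.15). Immediate early genes were higher for 11 of 24 members and lower for 2, or 14 and 3 adjusted over the list alone (adjusted p = 1.4e-07, and adjusted p = 0.46 with an estimated correlation). Mitosis genes were lower for 16 of 35, or 26 adjusted over the list alone (median -0.23, adjusted p = 4.3e-17, and adjusted p = 0.32 with an estimated correlation), PLK1 by -0.42, MKI67 by -0.37 and AURKA by -0.34.

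Part of the NRF2 list went the other way. SLC7A11 had an interaction of -1.44 ± 0.058 (adjusted p = 7.4e-07), TRIM16L of -0.92, OSGIN1 of -0.85 and NQO1 of -0.47 ± 0.044 (adjusted p = 3.7e-04). The pseudogene NMRAL2P, which is not on the list, had an interaction of -2.55. HMOX1 was at -0.026 ± 0.069 (adjusted p = 0.86). Of 32 NRF2 targets 7 were lower and 0 higher, or 11 and 2 adjusted over the list alone (median -0.11, adjusted p = 3.8e-04, and adjusted p = 0.15 with an estimated correlation). The list's call ended with a pseudocount of 5 (adjusted p = 0.14). Ribosomal protein genes were lower for 4 of 65, or 36 with 1 higher adjusted over the list alone (median -0.15, adjusted p = 3.9e-13, and adjusted p = 0.39 with an estimated correlation). DNA replication genes were higher for 5 of 38, or 18 adjusted over the list alone (median 0.10, adjusted p = 1.1e-07, and adjusted p = 0.32 with an estimated correlation), MCM6 by 0.36. ATF4 had an interaction of -0.29 (adjusted p = 0.0085), which lost its call without EV regular a (0.080) or EV glucose-deprived a (0.069). CCN1 had an interaction of -0.40 ± 0.052 (adjusted p = 0.0026). CCN2 was at -0.31 and lost its call without EV regular a (adjusted p = 0.079), EV regular b (0.062) or EV glucose-deprived b (0.069). Among the largest negative interactions, CNOT3 (-1.16), LINC01583 (-0.76) and KCNE4 (-0.68) lost their calls without EV glucose-deprived a (adjusted p = 0.078, 0.089 and 0.066) and without other EV libraries.

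Called lower in the interaction were also the lists of ATF4 targets (7 of 33 lower and 3 higher), YAP/TAZ targets (5 of 24 lower and 2 higher), aminoacyl-tRNA synthetases (2 of 19 lower) and oxidative phosphorylation (0 of 48 called). Adjusted over the list alone these counts were 11 and 5, 10 and 5, 4 and 0, and 0. Their adjusted p = 0.32 to 0.64 with an estimated correlation, fry did not call the last 2 (adjusted p = 0.28 and 0.11), and each call ended without EV regular b (adjusted p = 0.072 to 0.096) and without EV glucose-deprived a (0.061 to 0.14), among other libraries. Without EV regular a or b or EV glucose-deprived a or b, the lower ATF4 targets numbered 4, 4, 3 and 4 and the lower YAP/TAZ targets 1, 2, 2 and 1.

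In total the interaction was called for 563 genes, 301 higher and 262 lower, but 288 and 328 with median-of-ratios scaling and 300 and 312 with quantile normalization, so the larger direction depended on the scaling. Of the 563, 30 were higher and 4 lower by 1 or more on the log2 scale. Of the 301 genes, 242 were called higher in KO cells in glucose-deprived medium and 71 lower in regular medium. Of the 262, 200 were called lower in KO cells in glucose-deprived medium and 72 higher in regular medium. The count of 563 was 147 and 183 without EV regular a or b, 176 and 162 without EV glucose-deprived a or b, 1579 without KO glucose-deprived a and 368 without KO glucose-deprived b. With 1 library left out 16 to 18 heat shock genes were higher, 5 to 8 NRF2 targets lower, 4 to 22 mitosis genes lower, 7 to 14 immediate early genes higher, 1 to 11 DNA replication genes higher and 0 to 37 ribosomal protein genes lower.

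**Figure D3:**
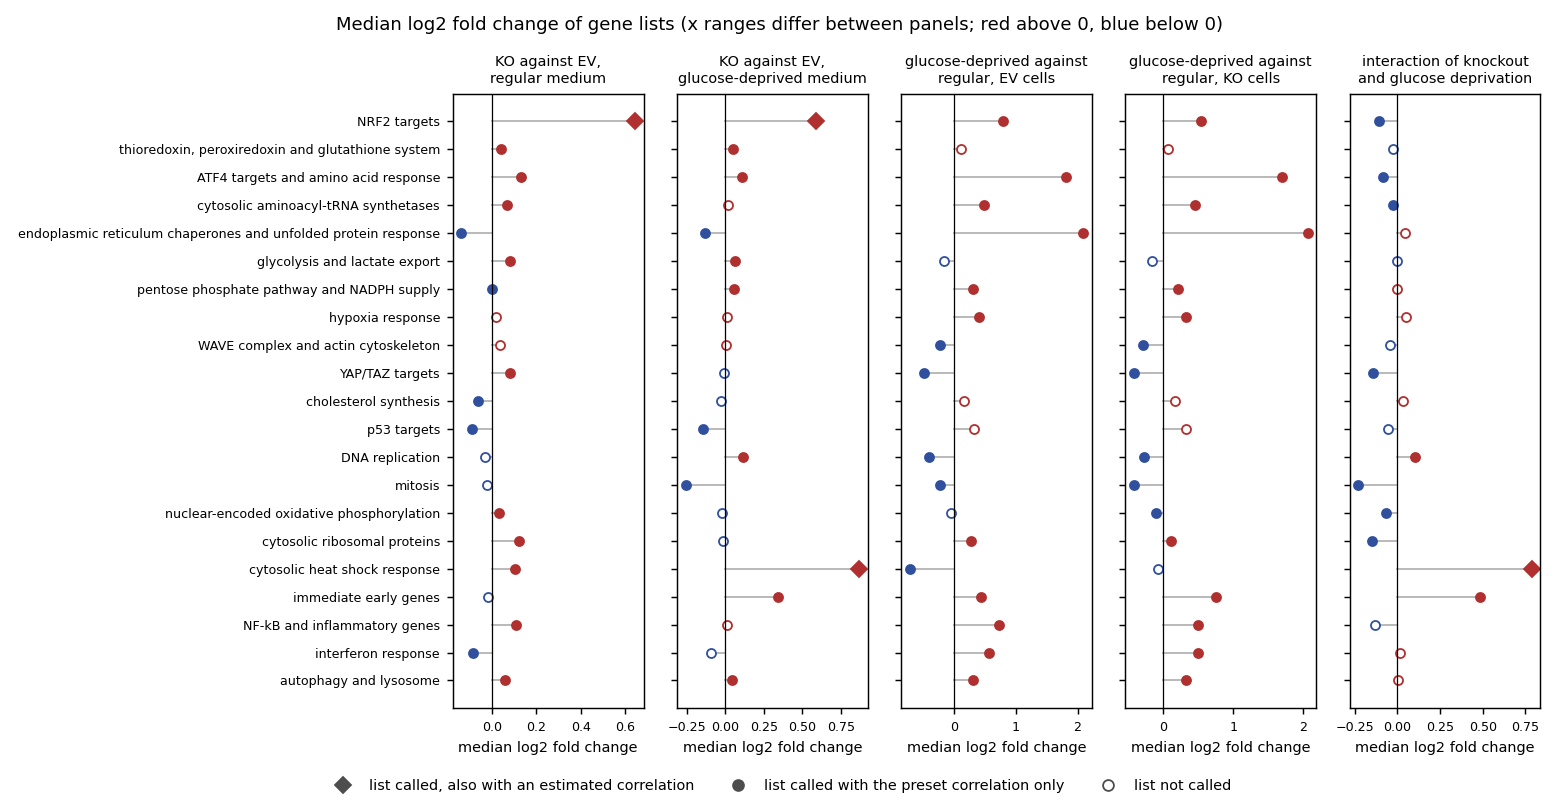
Median log2 fold change (x axis, with a range of its own in each panel) of the 21 gene lists called in at least 1 of the 5 comparisons. Filled symbols are lists called at the preset correlation and diamonds are those also called with an estimated correlation, which are NRF2 targets for KO against EV in both media and heat shock genes in the glucose-deprived medium (median 0.87) and in the interaction (0.79).

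Lists of selenoproteins, fatty acid synthesis, extracellular matrix and glioma and astrocyte markers were not called by camera in any of the 5 comparisons, nor were markers of other cell types (5 neuron, 6 epithelial and 10 fibroblast genes tested). The lowest camera adjusted p over these 7 lists was 0.060, for the epithelial markers in regular medium, where 1 of 6 members fell, or 2 adjusted over the list alone. Fry, which does not compare a list with other genes, called the glioma list for KO against EV in regular medium (5 of 12 lower and 1 higher, adjusted p = 0.0045). In glucose-deprived medium it called extracellular matrix genes (12 of 30 lower and 1 higher, adjusted p = 0.0072) and fibroblast markers (3 of 10 lower, adjusted p = 0.036). Without EV glucose-deprived a these members numbered 6 and 1, and without EV regular a the lower glioma members in regular medium numbered 3. On deprivation it called 5 of the 7 lists in EV cells (all but fatty acid synthesis and extracellular matrix) and 6 in KO cells (all but fibroblast markers), and none in the interaction. On deprivation of EV cells 10 of 18 selenoprotein genes fell and 3 rose (fry adjusted p = 0.0041).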

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

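All tests of explanations in this part were chosen only after the results were seen, and the interaction tests were not. Some outcomes of these tests, such as the calls of NRF2 targets, were thus known beforehand. The results here drew attention because the knockout effect differed between the media by the interaction test of limma. They comprise 47 named genes, 22 higher and 25 lower, and 10 gene lists. Of these, 30 genes and 6 lists were called in every fit that left out 1 library. Of the 6 lists only heat shock kept its call with an estimated correlation (adjusted p = 0.013, and 0.15 to 0.46 for the others).

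Called in each of those fits were the positive interactions of HSPA6 (2.24), ID2 (2.09), FOS (1.98), DNAJB1 (1.84), HSPH1 (1.63), EGR3 (1.51), RGS2 (1.5), DUSP1 (1.44), BAG3 (1.32), IER5 (1.24), DNAJA1 (0.95), MAF (0.61), HSPA8 (0.56), ATF3 (0.45), MCM6 (0.36) and XBP1 (0.33). The negative ones were FTL (-0.34), AURKA (-0.34), MKI67 (-0.37), TXNRD1 (-0.39), CCN1 (-0.40), PLK1 (-0.42), STC2 (-0.45), NQO1 (-0.47), PIF1 (-0.67), TRIM16 (-0.68), OSGIN1 (-0.85), TRIM16L (-0.92), SLC7A11 (-1.44) and NMRAL2P (-2.55). The lists were heat shock (median 0.79), immediate early genes (0.48), DNA replication (0.10), NRF2 targets (-0.11), ribosomal proteins (-0.15) and mitosis (-0.23).

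Without 1 library or another, the calls were lost of IER5L (1.84, highest adjusted p = 0.15), ID1 (0.90, 0.083), SMAD6 (0.77, 0.19), ID3 (0.64, 0.15), SOX2 (0.36, 0.089) and SLBP (0.30, 0.14). So were those of AARS1 (-0.23, 0.17), TKT (-0.28, 0.063), ATF4 (-0.29, 0.080), CCN2 (-0.31, 0.079), CCNB1 (-0.34, 0.057), KIF20A (-0.37, 0.059), WIPI1 (-0.38, 0.11), TMEM106A (-0.46, 0.12), KCNE4 (-0.68, 0.075), LINC01583 (-0.76, 0.089) and CNOT3 (-1.16, 0.078). The lists were aminoacyl-tRNA synthetases (median -0.025, highest adjusted p = 0.23), oxidative phosphorylation (-0.068, 0.11), ATF4 targets (-0.083, 0.14) and YAP/TAZ targets (-0.14, 0.21).

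Cytosolic heat shock genes were higher in KO than EV cells in glucose-deprived medium by a median of 0.87. On deprivation 16 of 19 fell and 3 rose in EV cells (median -0.72, camera adjusted p = 2.2e-04, and adjusted p = 0.14 with an estimated correlation). In KO cells 8 fell and 7 rose, so how far the gap came from falls in EV cells or rises in KO cells differed between members. A library out of place would leave a pair of libraries with little difference, but the medians of the 4 pairs of a KO and an EV library were 0.85, 0.85, 0.83 and 0.84 (smallest 0.825). Handling of the dishes before lysis stays open, since immediate early genes also rose, by a median of 0.341, alike in KO libraries a (0.307) and b (0.415), and the groups may have been handled apart. The call of that list was lost with an estimated correlation (adjusted p = 0.29), and its rising members went from 16 to 10 without EV glucose-deprived b. A joint effect of the lack of TrxR1 and of glucose is the biological candidate that the design names, and it was not tested. Another difference between the KO and EV cells could give the same pattern, since the number of knockout clones is not in the labels.

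TXNRD1 mRNA was near its control level in KO cells in regular medium. A KO library made up of EV cells alone would lack the rise of NRF2 targets. The 32 targets had medians of 0.666, 0.638, 0.565 and 0.558 above the EV mean in the 4 KO libraries. A share of EV cells within a KO library would leave part of the rise, so these medians cannot exclude it. These libraries may carry an edited gene that is still transcribed, which gene totals (-0.083) cannot tell apart from an unedited gene, since reads by exon and protein are not in the table. The lower level in glucose-deprived KO cells was not tested further.

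NRF2 targets were raised less by the knockout in glucose-deprived than in regular medium, by a median of -0.11. Of 32 members 7 were called lower, and the list's call was lost with an estimated correlation (adjusted p = 0.15). An upper limit of the measurement would leave few members able to rise, but 29 of 32 were higher in glucose-deprived KO than EV cells, and SLC7A11 at 506.1 CPM lay far below HSPA5 at 8796.2 CPM. The offset added before log2 is a source of such differences at low levels, but with the deposited offset of 0.023 CPM removed the median was -0.106, and no member moved by more than 0.014. With a larger offset of 5 CPM it was -0.056 (adjusted p = 0.14). A pathway that deprivation has already raised in EV cells may leave less room for the knockout, which was not tested.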

How the results depend on the processing

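The voom test was chosen after seeing the data, and the other alternatives were not. No paired analysis was possible because the table's columns carry no replicate numbers. The tests on counts with edgeR and DESeq2 were not run, although the recovered reads would have allowed them. When a library was left out, the lone library of its group was assumed to vary like the other groups.

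Of 447 values of named genes, 340 kept their direction and their side of the threshold under every alternative run, 107 changed side or sign under at least 1 and 4 of these changed sign. Of 70 calls of gene lists, 4 were kept under every alternative, 66 changed under at least 1 and 0 changed sign. The values of TXNRD1 in both media were kept under every alternative run for them. Fits without the variance trend, with robust estimation, with library weights or of the compared groups alone covered only the counts of called genes. Named genes, TXNRD1, shared calls and lists were not put to these fits, nor lists to voom. Voom called 900 genes for KO against EV in regular medium, 2548 in glucose-deprived medium, 9920 and 9604 for deprivation of EV and KO cells, and 506 for the interaction.

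Without the variance trend, 433 rather than 946 genes were called for KO against EV in regular medium and 223 rather than 563 for the interaction. With a 2-fold threshold added, the counts for KO against EV were 17 in regular and 35 in glucose-deprived medium, for deprivation 1237 in EV and 1019 in KO cells, and for the interaction 34. The shared calls were then 6 for the knockout and 863 for deprivation. With an estimated correlation the called lists numbered 1 and 2 for KO against EV in regular and glucose-deprived medium, 0 and 0 for deprivation of EV and KO cells, and 1 for the interaction. Fry, which does not compare a list with other genes, called 25 lists for deprivation of KO cells, and over all comparisons ended 6 calls of camera. The 2-fold threshold removes calls by construction, and for the trend the cause was not tested. The estimated correlation alone weakened 66 of the 70 list calls. It lowers the degrees of freedom of the test, so calls can end without a higher correlation between genes. How far correlated genes added to these losses was not tested.

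With 1 library left out, fewer libraries enter the fit. KO against EV in regular medium then gave 168 (without EV regular a) to 1414 calls (without KO glucose-deprived b), and 198, 517, 581 and 573 without EV regular b, KO regular a, and EV glucose-deprived a and b. In glucose-deprived medium it gave 852 (without EV glucose-deprived b) to 3058 (without KO regular a), and 892 and 1540 without EV glucose-deprived a and KO glucose-deprived b. The interaction gave 147 (without EV regular a) to 1579 (without KO glucose-deprived a), and 183, 176, 162 and 368 without EV regular b, EV glucose-deprived a and b, and KO glucose-deprived b. Shared knockout calls numbered 117 (without EV regular a) to 480 (without KO glucose-deprived a), and 134, 198 and 179 without EV regular b and EV glucose-deprived a and b. Lists called for the interaction numbered 6 (without EV regular b or EV glucose-deprived a) to 11.

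The values that changed sign were not called with all libraries. For KO against EV, ARRDC4 in regular medium (0.025) ranged from -0.035 to 0.086 with 1 library left out, and in glucose-deprived medium ASNS (-0.039) from -0.092 to 0.015 and CCN1 (0.027) from -0.016 to 0.071. The HMOX1 interaction (-0.026) ranged from -0.078 to 0.025, and with an offset of 5 CPM it was 0.39 (adjusted p = 0.0080). That offset is large beside the HMOX1 level in EV cells in regular medium (9.55 CPM), where it shrinks a fold change more than at higher levels.

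Another scaling moved the median of all genes by at most 0.038 on the log2 scale (-0.038, quantile normalization, deprivation of KO cells). These scalings, like the deposited one, align the libraries with each other, so a small shift was built in. A change of total mRNA per cell cannot be seen. With 76.2% of genes called on deprivation of EV cells and 73.3% of KO cells, rises and falls are relative to the scaling. At 1 read per 0.0095 to 0.0143 CPM, genes of 10 CPM or more rested on many reads in every library.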

Other observations

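The groups of genes in this part were chosen after their values were seen, and no explanation of them was tested. The camera p-values of these groups were adjusted over these groups alone. They come from the data that led to the choice, so they describe the groups and are no independent evidence of a change. Several targets of BMP signalling changed on glucose deprivation, in EV and KO cells to different extents. In EV cells 7 of 11 tested ID, SMAD and related genes fell and 4 rose, ID1 by -3.22, ID3 by -3.13, SMAD6 by -2.69 and ATOH8 by -1.66. Camera did not call the group there (adjusted p = 0.11). With quantile normalization 7 fell and 3 rose, and with median-of-ratios scaling 6 fell and 4 rose. In KO cells 5 fell and 4 rose on deprivation (median -0.017), and camera did not call the group (adjusted p = 0.62). In KO against EV cells in regular medium 0 were higher and 2 lower (median -0.24, camera adjusted p = 0.011, and adjusted p = 0.42 with an estimated correlation). In KO against EV cells in glucose-deprived medium 7 were higher and 2 lower (median 0.26, camera adjusted p = 4.4e-04, and adjusted p = 0.20 with an estimated correlation). The interaction was higher for 7 and lower for 0 (median 0.64, camera adjusted p = 1.5e-05, and adjusted p = 0.20 with an estimated correlation), or for 5 with quantile normalization. ID2 went apart from the others, falling in EV cells (-0.61) and rising in KO cells (1.48) on deprivation.

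Of 12 circadian clock genes 11 rose and 1 fell on deprivation of EV cells (median 0.41, camera adjusted p = 0.0025, and adjusted p = 0.14 with an estimated correlation), PER1 by 1.08 and NR1D1 by 1.13. In KO cells 9 rose and 1 fell (median 0.34, camera adjusted p = 0.011, and adjusted p = 0.23 with an estimated correlation). The time of day of the harvest is not in the labels. The COPI coat and TMED cargo receptor genes rose for 13 of 17 and fell for 1 in EV cells (median 0.34, camera adjusted p = 0.0025, and adjusted p = 0.18 with an estimated correlation). In KO cells 12 rose and 2 fell (camera adjusted p = 0.011, and adjusted p = 0.26 with an estimated correlation). In KO against EV cells in glucose-deprived medium 10 of them were lower and 0 higher (median -0.13, camera adjusted p = 2.3e-04, and adjusted p = 0.20 with an estimated correlation). In regular medium 2 were lower and the group was not called (adjusted p = 0.38), and in the interaction it was called lower (adjusted p = 0.00996, and 0.24 with an estimated correlation) with 0 members called.

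Of 34 proteasome subunit genes 22 fell and 2 rose on deprivation of EV cells (median -0.17, camera adjusted p = 0.0025, and adjusted p = 0.36 with an estimated correlation), and 22 fell and 1 rose in KO cells. In KO against EV cells in glucose-deprived medium 9 were higher and 2 lower (camera adjusted p = 2.3e-04, and adjusted p = 0.30 with an estimated correlation). In regular medium 2 were higher and 0 lower (camera adjusted p = 6.2e-06, and adjusted p = 0.42 with an estimated correlation), and the interaction had an adjusted p = 0.94. Of 13 tubulin genes 8 fell and 1 rose on deprivation of EV cells (median -0.50, camera adjusted p = 0.035, and adjusted p = 0.18 with an estimated correlation). In KO cells 8 fell and 2 rose, and the group was not called (adjusted p = 0.065). Of 26 small nucleolar RNA genes tested, 19 fell and 1 rose in EV cells (median -0.82) and 23 fell and 0 rose in KO cells (median -0.79). Their reads cannot be told apart from those of the host genes' introns without strand or position.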
